A study of Homo sapiens with 11 samples.

How the data were processed

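RNA sequencing was carried out on HCT-116 and RKO, established human colorectal cancer cell lines, after 24 h in phenylacetaldehyde (PAA), an aromatic aldehyde, or in medium with 0.1% dimethyl sulfoxide (DMSO) as vehicle. The labels give the time for PAA and none for the vehicle. The 11 libraries analysed here fall into 4 groups by the labels: HCT-116 with PAA (n = 3), HCT-116 with DMSO (n = 3), RKO with PAA (n = 3) and RKO with DMSO (n = 2, the replicates numbered 2 and 3). The PAA dose, and whether RNA was selected by poly(A) capture or by rRNA depletion, are not given in the sources used here. Per the labels' protocols, total RNA was extracted with Trizol and libraries followed standard Illumina procedures. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

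The deposited tables hold FPKM (fragment values scaled by transcript length and library depth) for 60612 genes and 229420 transcripts, calculated by the authors and named as FPKM per the file headers. The submitters' processing notes name cutadapt 1.9, FastQC and the genome build GRCh38. The aligner, the quantifier, the annotation release and the use of strand are not given in the sources used here. Absent signal is written in the tables as 0.0001, which was set to 0. A gene value was recomputed as the sum of isoform FPKM times isoform length, divided by the merged exon length of the gene. Where this exceeded an FPKM of 1, the gene value lay within 2% of it in 78.7% of gene and library pairs. The median ratio of gene value to isoform sum was 0.579. A change in isoform use can therefore move a gene value, and the isoform sum was tried as an alternative.

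FPKM values are not counts, so no count model was used as the main test. Counting depth was estimated from the value that 1 fragment adds in genes with a single transcript and came to 13650000 to 22780000 fragments per library. Among values of up to 10 fragments, only 21.6% to 25.2% per library were whole multiples of that step within a tolerance of 0.02 fragments, so whole reads were not recovered and no counting intervals are given. Between 11634 and 12133 genes per library reached an FPKM of 1. Totals of FPKM differed between libraries, from 264474 to 332021, so the choice of scaling can matter. None of the 10 housekeeping genes checked was at 0 in any library. An exact 0 is still reported only as a gene listed at 0, since it can be a failed estimate.

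Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1. A fold change on this scale understates the change of genes with low FPKM. The 13881 genes with an FPKM of at least 1 in at least 2 libraries were tested. A model with 1 mean per group was fitted to all 11 libraries, with 7 residual degrees of freedom and a prior of 1.82, and limma's moderated test with a mean-variance trend gave the PAA effect in each line and the difference between those effects, RKO minus HCT-116. P-values were adjusted by Benjamini-Hochberg and the threshold was an adjusted p of 0.05. All adjusted p-values for genes in the text come from this test, and are two-sided. The overlap of calls between the lines was set against the number that independent lists would share, with a one-sided Fisher's exact test. The lines share no control library. Genes are not independent replicates, and the shared estimate of spread can raise the overlap.

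The design, the alternatives, the rule for named genes and 29 gene lists (620 genes, all found in the tables) were fixed before the data were examined. The lists cover aldehyde metabolism, NRF2 targets, the integrated stress response, the unfolded protein response, the heat shock response, metallothioneins, p53 targets, DNA replication and G1-S, mitosis and G2-M, apoptosis regulators, cholesterol synthesis, fatty acid synthesis, Wnt targets, ribosome biogenesis, cytosolic ribosomal proteins, hypoxia and glycolysis, nuclear OXPHOS (oxidative phosphorylation), mitochondrially encoded genes, NF-kB inflammatory genes, the interferon response, MAPK output, AhR targets, lysosome and autophagy, ferroptosis and iron, colon differentiation, EMT (epithelial-mesenchymal transition) and adhesion, replication-dependent histones, markers of other cell types, and line identity. The last 2 were described and not tested. Of the others, 25 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 25 lists. Camera asks whether a list moved relative to the other genes. It was repeated with the correlation estimated from the data, and with fry, which tests whether a list's genes move, on balance, 1 way.

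The rule for named genes took, per line, the 6 genes that rose and the 6 that fell with the largest fold changes among called genes with a symbol whose PAA libraries all lay on 1 side of the DMSO libraries and whose mean FPKM was at least 1 in both groups or at least 2 in the higher one. It further took the 2 called members with the largest fold change of each list, or the member with the smallest p where none was called, the 4 genes with the smallest interaction p and a larger effect in each line, and CDKN1A, MYC, MKI67, HMOX1, DDIT3 and TXNIP in every case. Some genes that the rule took are not reported here. For lists that did not pass, only some of these members are named. Genes named outside this rule and outside the fixed lists were chosen after their values were seen and are said to be so. Gene positions are those of GENCODE 29 on GRCh38, in which 58394 of the gene identifiers and 205306 of the transcript identifiers were found. They give the gene span with its introns. Reads of near-identical copies or of overlapping genes may have been split or shared by the authors' quantification, and such genes are named as uncertain.

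The alternatives fixed beforehand were 2 other pseudocounts, 2 other filters on low values, 3 other scalings (a common total per library as in TPM, median-of-ratios factors, quantile normalization), each line fitted alone, array weights, the replicate number as a block, the sum of isoform FPKM, 2 stricter thresholds and leaving out each library in turn. A voom fit on estimated fragments and a scaling to a common total of nuclear genes were chosen after seeing the data. So was a fit after removing, per library, a spline trend on GC content and exon length. The test was checked on simulated values for the 13881 genes with 200 changed genes, 50 per fold size. It recovered 44%, 60%, 84% and 92% of genes changed 1.25-, 1.5-, 2- and 4-fold for the HCT-116 comparison and 30%, 50%, 72% and 88% for RKO, and 7.3% and 4.8% of the calls were false. Far fewer genes were changed there than the 6532 and 5553 called in the data. Since the adjustment depends on that share, these rates need not hold for the real comparisons. In the simulated data 2 of 100 random lists had a camera p under 0.05.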

Results

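The 11 libraries measured the transcriptome of HCT-116 and RKO cells after 24 h with phenylacetaldehyde (PAA) or with DMSO vehicle, for which the labels give no time. HCT-116 and RKO are colorectal cancer lines. Each HCT-116 group and the RKO group with PAA had 3 libraries, and RKO with DMSO had 2. The estimated depth was 13650000 to 22780000 fragments per library. The lines differed in EPCAM, an epithelial surface protein, which had an FPKM between 87.3 and 95.5 in the HCT-116 libraries and between 4.61 and 6.06 in the RKO libraries. Of the 6 line identity genes tested, 2 were higher with PAA in HCT-116, and 1 was higher and 1 lower in RKO. Of 17 markers of immune, blood, stromal and other cell types, 3 were expressed enough to test. None of the 3 passed in HCT-116 and 1 was lower in RKO by limma's test, and 1 more was higher when adjusted over the list alone.

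The first principal component, with 73.8% of the variance, separated the lines. Pearson correlations of log2(FPKM + 1) across genes were 0.976 to 0.985 within groups, 0.946 to 0.964 between treatments of a line and 0.792 to 0.831 between lines.

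In HCT-116, the question was which transcripts differ between PAA and vehicle. Genes of the integrated stress response and NRF2 targets rose with PAA. HMOX1, which encodes heme oxygenase 1, went from an FPKM of 17.4 ± 0.57 to 166 ± 4.61 (SD, n = 3 each), a log2 fold change of 3.19 ± 0.038 (SE). PPP1R15A, the stress-induced phosphatase subunit that reverses eIF2α phosphorylation, went from 14.4 ± 0.48 to 118 ± 1.05, and SRXN1, which repairs oxidised peroxiredoxins, from 57.3 ± 0.22 to 443 ± 4.88. Genes of DNA replication and Wnt target genes fell. WNT16, a secreted Wnt ligand, dropped from 32.5 ± 0.077 to 2.07 ± 0.35, and RNF43, a ubiquitin ligase that removes Wnt receptors, had a log2 fold change of -2.05 ± 0.043. Of 13881 genes tested, 6532 (47.1%) passed the threshold, 3019 higher and 3513 lower with PAA (limma, Benjamini-Hochberg). An absolute log2 fold change of at least 1 was reached by 409 of them, 184 higher and 225 lower. The share of higher genes among the calls was 46.2% and became 61.3% when libraries were scaled to a common total and 38.1% with a common total of nuclear genes, a scaling chosen after seeing the data.

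The largest rises included UPP1, uridine phosphorylase 1 (chromosome 7, 48088628 to 48108733), with a log2 fold change of 3.31 ± 0.053 (SE; limma, adjusted p = 8.17e-10). HMOX1 lies on chromosome 22 at 35380361 to 35394214 (adjusted p = 1.81e-10). CYP4F11, a cytochrome P450 of fatty acid hydroxylation, rose by 3.10 ± 0.048 from an FPKM of 3.70 ± 0.24 to 39.2 ± 0.80. SPRR2D, a small proline-rich protein of the cornified envelope, was listed at 0, 0 and 0.043 in the DMSO libraries and at 6.69, 6.08 and 8.02 with PAA. Both belong to families of near-identical genes, so reads may be shared with relatives. Among the largest falls, WNT16 (chromosome 7, 121325367 to 121341104) had a log2 fold change of -3.45 ± 0.076 (adjusted p = 5.04e-09). ADAM19, a metalloprotease, had -3.33 ± 0.19, and TNFRSF6B, a decoy receptor for Fas ligand that overlaps RTEL1, had -3.34 ± 0.69, with -2.32 without PAA replicate 1. CYP24A1, the enzyme that inactivates vitamin D (chromosome 20, 54153449 to 54173973), dropped from 15.1 ± 0.72 to 0.718 ± 0.069. The transcription factor SOX4 dropped from 31.2 ± 1.43 to 3.96 ± 0.11, and the nuclear receptor NR2F1 from 17.3 ± 0.33 to 1.98 ± 0.081.

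The integrated stress response list, genes induced through eIF2α phosphorylation and ATF4, had 25 members higher and none lower among 29 tested, with a median log2 fold change of 1.05 (limma camera, adjusted p = 5.75e-16). It had 26 higher when adjusted over the list alone. DDIT3, which encodes the transcription factor CHOP, rose from an FPKM of 6.79 ± 2.16 to 47.1 ± 4.74, and TRIB3, a pseudokinase induced by ATF4, from 16.0 ± 0.24 to 84.7 ± 1.84. Among NRF2 targets, the antioxidant genes that include HMOX1 and SRXN1, 19 of 27 rose and 2 fell (median 0.64, adjusted p = 1.66e-09), with 20 higher and 2 lower adjusted over the list alone. SLC7A11, the cystine importer, rose from 15.7 ± 0.85 to 64.3 ± 1.71. In the unfolded protein response list 16 of 21 rose and 3 fell (median 0.32, adjusted p = 0.000627), and 16 and 4 adjusted over the list alone. HSPA5, the main chaperone of the endoplasmic reticulum, rose from 276 ± 3.25 to 638 ± 3.66, and its cochaperone DNAJB9 from 5.30 ± 0.37 to 14.3 ± 0.92. The heat shock response list moved the other way, with 14 of 19 lower and 1 higher (median -0.25, adjusted p = 0.000224), or 15 and 1 adjusted over the list alone, and a median of -0.14 with 10 lower under a common total. HSPA1B, an Hsp70 gene whose reads can be shared with its near-identical copy HSPA1A, had a log2 fold change of -0.81 ± 0.031, and HSPE1, the mitochondrial co-chaperonin, had -0.58 ± 0.15.

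DNA replication and G1-S genes fell in HCT-116, with 31 of 34 lower and none higher (median -0.77, limma camera, adjusted p = 2.63e-13), and the same count adjusted over the list alone. CCNE2, the G1-S cyclin E2, dropped from 6.27 ± 0.39 to 1.71 ± 0.30 and the transcription factor E2F2 from 7.32 ± 0.54 to 2.56 ± 0.28. The mitosis and G2-M list did not pass (median 0.11, adjusted p = 0.0941), although 11 of its 30 members were higher and 5 lower, or 11 and 6 adjusted over the list alone. Its median was 0.21 with 17 higher and 4 lower under a common total, and 0.06 with 9 and 7 under a common nuclear total, chosen after seeing the data. CDC20, the activator of the anaphase-promoting complex, rose from 123 ± 3.57 to 195 ± 1.72, and HMMR, a spindle and hyaluronan-binding protein, rose by 0.54 ± 0.050 on the log2 scale. CDK1, the mitotic kinase, fell from 22.4 ± 1.71 to 15.9 ± 1.75. Of the Wnt targets, 11 of 14 fell and none rose (median -0.49, adjusted p = 5.39e-05), also when adjusted over the list alone. SOX9, a transcription factor of intestinal crypts, dropped from 48.2 ± 0.29 to 12.6 ± 0.39. The 6 lists named so far with an adjusted p past the threshold also passed with an estimated correlation.

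Another 7 lists passed with the preset correlation only. All 13 mitochondrially encoded coding genes fell (median -0.51, limma camera, adjusted p = 2.61e-08), and the adjusted p = 0.129 with an estimated correlation. With quantile normalization the median was -0.15 and 8 genes were lower. MT-ND3, a subunit of complex I, had a log2 fold change of -0.75 ± 0.062. Mitochondrial transcripts made up 39.3% ± 1.01 of all FPKM with DMSO and 31.3% ± 0.10 with PAA (SD, n = 3 each), with no overlap between the groups. Of the nuclear OXPHOS genes 16 of 28 fell and none rose (median -0.21, adjusted p = 0.000663), with a median of -0.11 and 8 lower under a common total, and the adjusted p = 0.0849 with an estimated correlation. SDHA, the flavoprotein of complex II, dropped from 14.6 ± 0.23 to 8.11 ± 0.23. ATP5F1A, a subunit of ATP synthase, had a log2 fold change of -0.48 ± 0.059, and of -0.22 with no call when isoform values were summed. Cytosolic ribosomal proteins rose, 18 of 26 with none lower (median 0.31, adjusted p = 8.78e-08), and the adjusted p = 0.0849 with an estimated correlation. RPL3 rose from 266 ± 20.5 to 412 ± 22.1 and RPL10A from 258 ± 3.92 to 378 ± 16.0. The counts of these 3 lists were the same adjusted over the list alone.

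Among the metal-binding metallothioneins 4 of 6 rose and none fell (median 0.38, limma camera, adjusted p = 0.0103), and the adjusted p = 0.0707 with an estimated correlation. MT2A rose from 484 ± 28.9 to 857 ± 50.4 and MT1X from 21.5 ± 0.43 to 39.5 ± 0.60. Of the interferon response genes 10 of 18 fell and 1 rose (median -0.33, adjusted p = 0.0103), and the adjusted p = 0.0707 with an estimated correlation. OAS3, an antiviral oligoadenylate synthetase, had a log2 fold change of -1.16 ± 0.051 and IFI6 of -0.88 ± 0.18. Ribosome biogenesis genes fell more often than they rose, 12 against 3 of 25 (median -0.15, adjusted p = 0.0381), with a median of -0.04, 7 lower and 4 higher under a common total, and the adjusted p = 0.231 with an estimated correlation. UTP20, a factor for small-subunit processing, had -0.64 ± 0.052, and POLR1B, a subunit of RNA polymerase I, had -0.62 ± 0.077, with -0.35 and no call when isoforms were summed. In the ferroptosis and iron list 8 of 16 rose and 3 fell (median 0.09, adjusted p = 0.0328), and the adjusted p = 0.0849 with an estimated correlation. That median was 0.20 with a common total, 0.04 with a common total of nuclear genes, chosen after seeing the data, and 0.15 without DMSO replicate 2. Its risers included CHAC1, which degrades glutathione, from 8.24 ± 0.44 to 40.2 ± 0.82. The list shares CHAC1 and SLC7A11 with the integrated stress response and HMOX1, SLC7A11, FTH1 and FTL with NRF2 targets. It is therefore not independent of those lists. Adjusted over the list alone, 4 metallothioneins, 8 ferroptosis genes and 3 ribosome biogenesis genes rose, and 11 interferon genes fell.

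The other lists did not pass in HCT-116, and single members did. Of 20 aldehyde metabolism genes, 7 rose and 9 fell (median -0.24, limma camera, adjusted p = 0.325), or 7 and 10 adjusted over the list alone, and the median was -0.14 under a common total. ALDH1A3, which oxidises retinaldehyde to retinoic acid, dropped from an FPKM of 109 ± 3.42 to 19.7 ± 0.40, and AKR1B10, an aldo-keto reductase, rose from 0.518 ± 0.21 to 5.52 ± 0.73. Among p53 targets 6 of 28 rose and 11 fell, or 6 and 12 adjusted over the list alone. The p53 list median was -0.08 and became 0.02 when libraries were scaled to a common total (adjusted p = 0.402). GADD45A, a stress-response gene of growth arrest, rose from 26.7 ± 1.15 to 85.3 ± 2.79, and TNFRSF10B, the death receptor DR5, from 32.2 ± 0.49 to 69.9 ± 0.62. CDKN1A, the cell cycle inhibitor p21, had a mean of 140 ± 22.8 with DMSO and 180 ± 12.4 with PAA and did not pass (adjusted p = 0.0892). MYC varied too widely to compare, from 3.69 to 23.2 with PAA. SQSTM1, the autophagy receptor p62, rose from 77.8 ± 2.19 to 257 ± 0.54, although its lysosome and autophagy list did not pass (8 higher and 3 lower of 26, or 8 and 2 adjusted over the list alone; adjusted p = 0.0523). CXCL8, the chemokine interleukin-8, rose from 0.952 ± 0.32 to 6.27 ± 0.44, and its NF-kB inflammatory list also missed the threshold (7 higher and 2 lower of 14, or 9 and 3 adjusted over the list alone; adjusted p = 0.0523).

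The remaining lists of HCT-116 were EMT and adhesion (5 higher, 1 lower of 15; limma camera, adjusted p = 0.0565), hypoxia and glycolysis (5 and 13 of 26; 0.094), cholesterol synthesis (7 and 4 of 26; 0.177), MAPK output (8 and 8 of 24; 0.229), apoptosis regulators (8 and 6 of 27; 0.325), histones (3 and 0 of 11; 0.325) and fatty acid synthesis (3 and 4 of 12; 0.390). Adjusted over the list alone, these counts changed only for MAPK output, to 9 lower. Under a common total more were higher, 11 and 4 for cholesterol synthesis, 10 and 6 for MAPK output and 10 and 4 for apoptosis regulators, and hypoxia and glycolysis had 5 and 9. AhR targets had 2 tested members, 1 higher and 1 lower, and colon differentiation had 4, with 2 lower or 3 adjusted over the list alone, too few for a list test. The labels give no dose, so the size of these changes belongs to 1 unstated exposure.

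**Figure D1:**
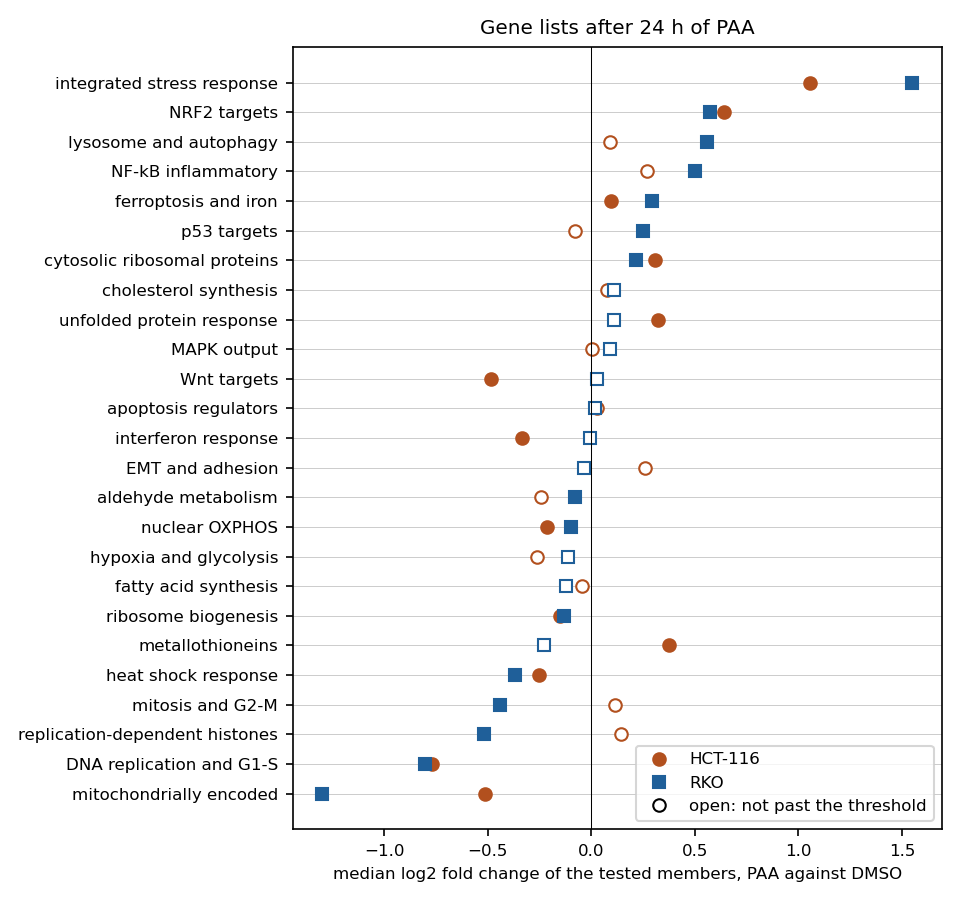
Median log2 fold change of FPKM + 1 with PAA against DMSO (horizontal axis) for the 25 tested gene lists (vertical axis), in HCT-116 (circles) and RKO (squares). Filled symbols passed limma's camera test with the preset correlation, the integrated stress response lies furthest to the right in both lines, and the RKO medians of aldehyde metabolism, nuclear OXPHOS, ribosome biogenesis, hypoxia, fatty acid synthesis, interferon and EMT turn positive, as the HCT-116 median of p53 targets and fatty acid synthesis does, when libraries are scaled to a common total. The medians of Wnt targets and apoptosis regulators in RKO, of MAPK output in HCT-116 and of apoptosis regulators in HCT-116 also change sign under at least 1 other scaling.

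In RKO, PAA again raised the integrated stress response and NRF2 targets and lowered DNA replication and mitochondrially encoded genes, and it also lowered mitotic genes. SLC7A11, the cystine importer, went from an FPKM of 2.08 ± 0.22 (SD, n = 2) to 34.7 ± 0.12 (SD, n = 3), a log2 fold change of 3.54 ± 0.055 (SE). CHAC1 went from 0.846 ± 0.18 to 17.1 ± 1.04, and ASNS, asparagine synthetase, from 7.70 ± 1.06 to 63.5 ± 4.89. MT-ND5 and MT-ND6, subunits of complex I, went from 3066 ± 96.3 to 762 ± 8.08 and from 3863 ± 240 to 957 ± 22.5. MAP1LC3C, an autophagy protein of the LC3 family, went from 107 ± 2.45 to 4.91 ± 0.26. Of 13881 genes, 5553 (40.0%) passed, 3569 higher and 1984 lower with PAA (limma, Benjamini-Hochberg), and 286 of them reached an absolute log2 fold change of 1, 177 higher and 109 lower. The share of higher genes was 64.3% and depended on the scaling. It was 90.4% with a common total per library, which includes mitochondrial genes, and 61% with a common total of nuclear genes, chosen after seeing the data. With median-of-ratios factors it was 50.5% and with quantile normalization 50.1%. The common total moved the median log2 fold change of all genes from 0.06 to 0.28, and 34 genes called as reported were called in the opposite direction with it.

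SLC7A11 lies on chromosome 4 at 138164097 to 138242349 (limma, adjusted p = 1.91e-09), CHAC1 on chromosome 15 at 40952962 to 40956519 (adjusted p = 1.63e-08), ASNS on chromosome 7 at 97852118 to 97872542 (adjusted p = 4.57e-07) and TRIB3 on chromosome 20 at 362835 to 397559, with a log2 fold change of 2.87 ± 0.040. The other large rises are uncertain in their source. MIR22 is a microRNA of 85 bp inside a longer host transcript, and its value went from 0.141 ± 0.015 to 11.6 ± 3.55. RPL32P29 is a pseudogene of a ribosomal protein gene and went from 0.408 ± 0.039 to 13.5 ± 1.73, with no call without DMSO replicate 3 (adjusted p = 0.0506). SST, which encodes the hormone somatostatin, was listed at 58.5 and 11.1 in the DMSO libraries and at 0 in each PAA library. MAP1LC3C (chromosome 1, 241995490 to 241999073) had a log2 fold change of -4.20 ± 0.095 (adjusted p = 1.74e-08), and METTL7B, a methyltransferase of lipid droplets, had -2.38 ± 0.068. MTND4P12, a nuclear pseudogene on chromosome 5 that can share reads with MT-ND4, had -2.10 ± 0.20. MT-ND5 spans positions 12337 to 14148 of the mitochondrial chromosome and MT-ND6 positions 14149 to 14673, on the opposite strand.

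Of the integrated stress response list 27 of 29 rose and none fell (median 1.55, limma camera, adjusted p = 3.13e-18), with the same count adjusted over the list alone. DDIT3 rose from 12.6 ± 0.43 to 44.7 ± 4.44. Of the NRF2 targets 17 of 27 rose and 1 fell (median 0.57, or 0.86 with a common total, adjusted p = 4.32e-06), or 18 and 1 adjusted over the list alone, and HMOX1 rose from 38.4 ± 1.58 to 147 ± 3.59. The unfolded protein response list did not pass (median 0.11, adjusted p = 0.758), with 11 members higher and 7 lower of 21 on either adjustment. Its median was 0.38 with 12 higher and 2 lower under a common total, 0.02 with median-of-ratios factors and 0.22 without DMSO replicate 2. Its members XBP1, a transcription factor of that response, and DNAJB9 rose by 1.39 ± 0.12 and 1.06 ± 0.077 on the log2 scale. The heat shock list had 14 of 19 lower and none higher (median -0.37, adjusted p = 8.62e-10), or 16 lower adjusted over the list alone. With a common total the heat shock median was -0.09, with 7 lower and 4 higher. SERPINH1, a collagen chaperone, dropped from 39.1 ± 2.22 to 21.3 ± 2.70, and HSPE1 from 162 ± 56.8 to 63.0 ± 4.35, a log2 fold change of -1.30 that ranged from -1.67 without DMSO replicate 2 to -0.94 without DMSO replicate 3. Among p53 targets 16 of 28 rose and 1 fell (median 0.25, adjusted p = 0.000655), or 18 and 2 adjusted over the list alone, and the p53 median was 0.47 with a common total and 0.14 with quantile normalization. BBC3, the pro-apoptotic protein PUMA, rose from 4.41 ± 0.21 to 13.2 ± 1.2 and GADD45A from 31.2 ± 4.19 to 82.6 ± 14.4. CDKN1A went from 42.1 ± 2.61 to 68.4 ± 16.0 (adjusted p = 0.0163), a call that ended without DMSO replicate 2 (adjusted p = 0.0963) and without DMSO replicate 3 (adjusted p = 0.0528).

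In the DNA replication and G1-S list 31 of 34 fell and 1 rose (median -0.80, limma camera, adjusted p = 2.34e-20), or 32 and 1 adjusted over the list alone. CCNE2 dropped from 13.3 ± 0.61 to 4.22 ± 0.21. In the mitosis and G2-M list 22 of 30 fell and 2 rose (median -0.44, adjusted p = 2.58e-12), or 23 and 2 adjusted over the list alone. With a common total the mitosis median was -0.18, with 15 lower and 4 higher. CDK1 dropped from 18.2 ± 0.72 to 8.68 ± 0.53, and MKI67, the proliferation marker Ki-67, from 29.6 ± 2.69 to 14.6 ± 3.10, a call that ended without DMSO replicate 2 (adjusted p = 0.0676). In HCT-116, MKI67 had a log2 fold change of -0.57 that did not pass (limma, adjusted p = 0.055). That value ranged from -0.77 to -0.39 with 1 library left out, so a fall of MKI67 was not particular to RKO. Of the lysosome and autophagy genes 20 of 26 rose and none fell (median 0.56, adjusted p = 6.83e-07), or 22 adjusted over the list alone. WIPI1, an early autophagosome protein, rose from 3.36 ± 0.21 to 10.2 ± 0.21 and GABARAPL2, an ATG8-family protein, from 13.2 ± 1.19 to 32.2 ± 3.70. All 13 mitochondrially encoded coding genes fell (median -1.30, adjusted p = 1.09e-19), with a median of -0.36 and 9 genes lower under quantile normalization. Their share of FPKM, with rRNA and tRNA included, was 34.4% ± 0.79 with DMSO (SD, n = 2) and 18.4% ± 0.17 with PAA (SD, n = 3). In RKO the lists that also passed with an estimated correlation were the integrated stress response, NRF2 targets, heat shock, p53 targets, DNA replication, mitosis, lysosome and autophagy, and the mitochondrially encoded genes.

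**Figure D2:**
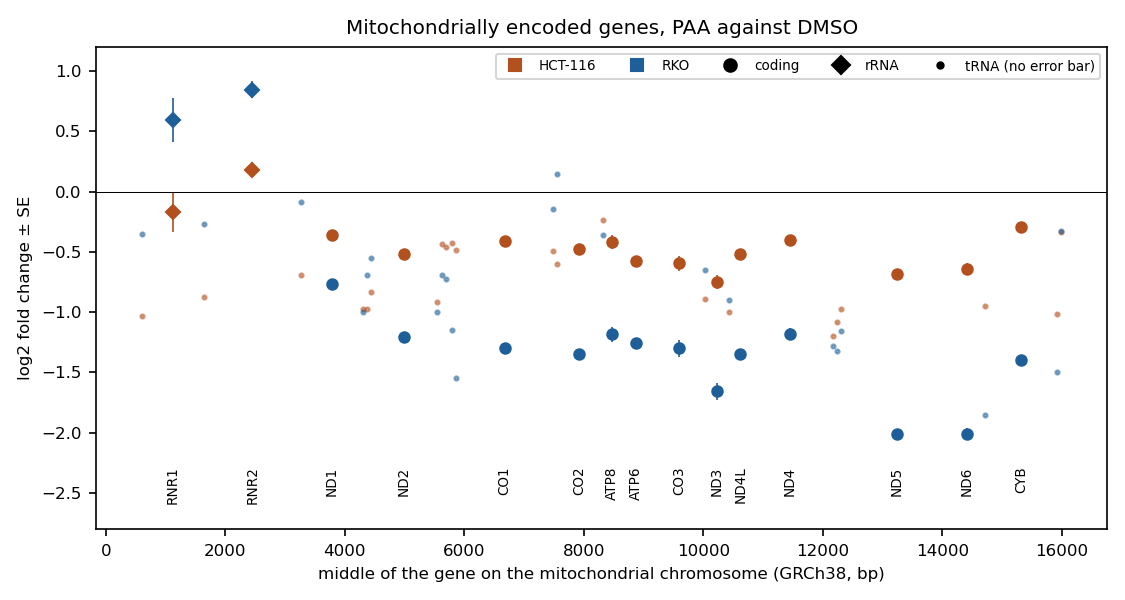
Log2 fold change with PAA against DMSO (vertical axis) of each gene of the mitochondrial chromosome at the middle of its position in bp (horizontal axis), in HCT-116 (orange) and RKO (blue), with standard errors for coding genes (circles) and rRNA genes (diamonds). Each of the 13 coding genes lies below 0 in both lines, between -0.75 and -0.295 in HCT-116 and between -2.01 and -0.765 in RKO.

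Another 7 lists passed in RKO with the preset correlation only. NF-kB inflammatory genes had 10 of 14 higher and none lower (median 0.50, limma camera, adjusted p = 0.000225), or 10 and 1 adjusted over the list alone, and the adjusted p = 0.0563 with an estimated correlation. CXCL8 rose from 0.709 ± 0.039 to 3.62 ± 0.34 and RELB, an NF-kB subunit, from 6.04 ± 0.73 to 16.8 ± 0.35. In the ferroptosis and iron list 8 of 16 rose and 2 fell (median 0.29, or 0.57 with a common total, adjusted p = 0.00859), with the same counts adjusted over the list alone and an adjusted p = 0.0517 with an estimated correlation. As in HCT-116, this list is not independent of the integrated stress response and NRF2 targets, with which it shares members such as SLC7A11. Cytosolic ribosomal proteins had 16 of 26 higher and none lower on either adjustment (median 0.22, or 0.50 with a common total and 0.13 with median-of-ratios factors, adjusted p = 0.000318), and the adjusted p = 0.18 with an estimated correlation. RPL3 rose by 0.62 ± 0.13 on the log2 scale, a call that ended without DMSO replicate 3 (adjusted p = 0.055), and RPL10A by 0.39 ± 0.039. Nuclear OXPHOS genes had 12 of 28 lower and none higher on either adjustment, with a median of -0.10 that became 0.18 with a common total, -0.19 with median-of-ratios factors and -0.15 without DMSO replicate 3 (adjusted p = 0.000378), and the adjusted p = 0.0632 with an estimated correlation. SDHA fell by 0.44 on the log2 scale, and ATP5F1A had -0.57 ± 0.066, which turned to 0.30 with no call when isoform values were summed.

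Ribosome biogenesis genes had 11 of 25 lower and 1 higher, or 12 and 2 adjusted over the list alone, with a median of -0.13 that became 0.15 with a common total and -0.22 with median-of-ratios factors (limma camera, adjusted p = 0.0014), and the adjusted p = 0.0948 with an estimated correlation. RRP12, a ribosomal RNA processing factor, rose from 13.1 ± 1.10 to 21.2 ± 1.08. BYSL, a small-subunit assembly factor, had -0.52 ± 0.15 and lost its call without PAA replicate 1, DMSO replicate 2 or DMSO replicate 3 (adjusted p = 0.0665, 0.0612 and 0.128). Of 20 aldehyde metabolism genes 3 rose and 4 fell on either adjustment, with a median of -0.08 that became 0.04 with a common total and -0.13 with median-of-ratios factors or without PAA replicate 3 (adjusted p = 0.0298), and the adjusted p = 0.0726 with an estimated correlation. ALDH1B1, a mitochondrial aldehyde dehydrogenase, dropped from 36.5 ± 1.08 to 21.1 ± 0.51. ALDH5A1, succinic semialdehyde dehydrogenase, had -0.63 ± 0.15, with no call without DMSO replicate 3 (adjusted p = 0.0524) and 0.12, also without a call, when isoforms were summed. Replication-dependent histones had 4 of 11 lower and 2 higher on either adjustment (median -0.52, adjusted p = 0.0491), and the adjusted p = 0.189 with an estimated correlation. That list passed narrowly and missed the threshold without 7 of the 11 libraries, taken 1 at a time, with an adjusted p of up to 0.187 and a median of -0.23 without RKO DMSO replicate 3. With a common total its median was -0.29. The linker histone gene H1-2 dropped from 58.7 ± 0.69 to 24.7 ± 0.75 and the core histone gene H2AC20 from 3.98 ± 0.70 to 0.969 ± 0.43. Because most histone mRNAs lack a poly(A) tail, their recovery depends on how RNA was selected, which the labels do not state.

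Lists that did not pass in RKO also had changed members. Of the metallothioneins 1 of 6 rose and 3 fell on either adjustment (median -0.23, limma camera, adjusted p = 0.0594), with MT1M dropping from 53.9 ± 0.97 to 17.8 ± 1.63. That median was -0.02 under a common total and -0.01 under quantile normalization, each with 2 higher and 2 lower. Wnt targets had 3 of 14 higher and 2 lower, or 2 and 2 adjusted over the list alone, and a median of 0.03 that became -0.02 with median-of-ratios factors (adjusted p = 0.652). CCND1, the G1 cyclin D1, dropped from 38.5 ± 3.27 to 23.3 ± 2.14, and CD44, an adhesion receptor, went from 4.39 ± 0.71 to 7.46 ± 0.71, with no call without DMSO replicate 3 (adjusted p = 0.0667). LDHA, lactate dehydrogenase A, dropped from 108 ± 2.74 to 43.6 ± 2.36 in the hypoxia and glycolysis list (5 higher, 8 lower of 26 on either adjustment; adjusted p = 0.0678). The others were fatty acid synthesis (2 higher, 5 lower of 12; 0.0685), cholesterol synthesis (9 and 2 of 26; 0.322), the interferon response (6 and 3 of 18; 0.582), MAPK output (8 and 3 of 24; 0.652), EMT and adhesion (5 and 3 of 15; 0.676) and apoptosis regulators (7 and 2 of 27; 0.892). Adjusted over the list alone, interferon and MAPK output had 4 lower. Under a common total the counts were 10 higher and 4 lower for hypoxia and glycolysis, 18 and 0 for cholesterol synthesis, 15 and 2 for MAPK output, 11 and 1 for apoptosis regulators, 8 and 3 for interferon, 4 and 3 for fatty acid synthesis and 6 and 2 for Wnt targets. AhR targets had 1 higher and 1 lower of 2, and colon differentiation 1 higher and 3 lower of 4, too few for a list test. TXNIP, a thioredoxin inhibitor, went from 13.5 ± 1.18 to 8.92 ± 0.55 (adjusted p = 0.0236), a call lost without DMSO replicate 2, DMSO replicate 3 or PAA replicate 2 (adjusted p = 0.141, 0.0563 and 0.0663) and with a common total (0.173). MYC ranged from 7.77 to 42.0 in the 2 DMSO libraries and from 8.24 to 73.8 with PAA.

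The comparison of the PAA effect between the lines showed a shared response and genes that moved apart. Of the genes called in both lines, 2932 of 3486 (84.1%) had the same direction, 1721 higher in both and 1211 lower in both. Independent lists of these sizes would share 776.2 and 502.1, which gives odds ratios of 6.47 and 6.53 (one-sided Fisher's exact test, p = 2.66e-298 for the shared falls, and below the smallest number the software writes for the shared rises). With each line fitted alone, 1445 and 1045 genes were shared, where 669.9 and 429.7 would be by independence. Across genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson correlation of 0.427 and a Spearman correlation of 0.446.

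**Figure D3:**
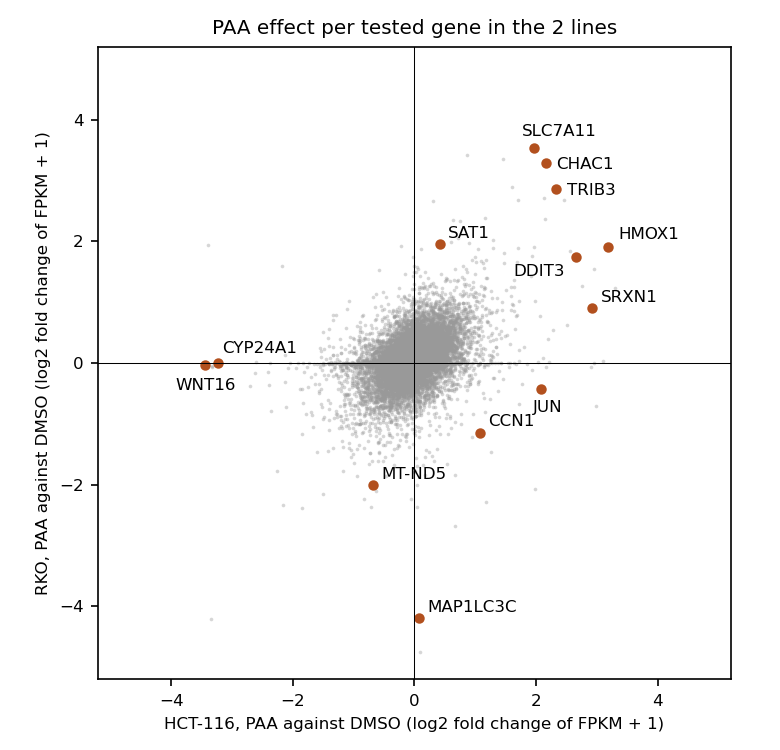
Log2 fold change of FPKM + 1 with PAA against DMSO in HCT-116 (horizontal axis) and in RKO (vertical axis) for the 13881 tested genes (grey points), with 13 named genes in orange. SLC7A11, CHAC1, TRIB3, DDIT3, HMOX1 and SRXN1 lie in the upper right, and JUN and CCN1 lie to the right of 0 and below it.

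The effect differed between the lines for 4307 genes, 2963 with a higher log2 fold change in RKO and 1344 with a lower one (limma interaction contrast, Benjamini-Hochberg). The share with a higher value in RKO was 68.8%. It became 73.8% with a common total of nuclear genes, chosen after seeing the data, and 86.0% with a common total. It was 55.9% with median-of-ratios factors and 53.4% with quantile normalization. The common total moved the median difference of all genes from 0.08 to 0.21. JUN, an AP-1 transcription factor (chromosome 1, 58780788 to 58784327), rose from 8.32 ± 0.43 to 38.3 ± 0.75 in HCT-116 and fell from 259 ± 0.34 to 191 ± 1.14 in RKO, an interaction of -2.51 ± 0.053 (SE; adjusted p = 3.60e-08). CCN1, a secreted matricellular protein, rose from 2.76 ± 0.31 to 6.93 ± 0.30 and fell from 48.6 ± 0.95 to 21.5 ± 0.50. SAT1, which acetylates polyamines, rose in both lines and more in RKO, by 0.42 ± 0.042 and 1.95 ± 0.047 on the log2 scale. CYP24A1 was listed at 0 in all RKO libraries, so its fall in HCT-116 has no counterpart to compare.

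Of the 25 lists, 11 differed between the lines by limma's camera. The mitosis and G2-M genes had lower values in RKO for 23 of 30 and higher for none (median difference -0.50, adjusted p = 1.41e-16), and the median was -0.35 with 20 lower under a common total. The mitochondrially encoded genes were lower for all 13 (-0.83, adjusted p = 4.62e-17), and the adjusted p = 0.0516 with an estimated correlation. With quantile normalization their median was -0.19, with 8 lower and 1 higher. Metallothioneins were lower for 4 of 6 and higher for 1 (-0.80, adjusted p = 0.00164), since MT1X and MT2A rose in HCT-116 and fell in RKO, where MT2A had a value of 0.13 with no call under quantile normalization. That scaling gave the metallothioneins a median of -0.31, with 3 lower. Unfolded protein response genes were lower for 10 of 21 and higher for 1 (-0.21, adjusted p = 0.000122), and NRF2 targets lower for 12 of 27 and higher for 4 (-0.19, adjusted p = 0.000664). Both differences nearly vanished with a common total, to -0.05 with 4 lower and 2 higher for the unfolded protein response and -0.02 with 10 lower and 8 higher for NRF2 targets. That total includes mitochondrial FPKM, whose share fell further in RKO. With a common total of nuclear genes, chosen after seeing the data, the medians were -0.19 with 9 lower and 2 higher, and -0.16 with 12 lower and 5 higher. With median-of-ratios factors they were -0.30 and -0.27. The NRF2 median ranged from -0.29 without HCT-116 PAA replicate 3 to -0.10 without RKO PAA replicate 1. Higher in RKO were p53 targets, 17 of 28 against 1 lower (0.37, adjusted p = 0.000363), and Wnt targets, 10 of 14 against none (0.68, adjusted p = 0.000113). Adjusted over the list alone, the counts were 2 and 11 for the unfolded protein response, 6 and 12 for NRF2 targets, 18 and 1 for p53 targets, and the same for the others. RNF43 and SOX9 fell in HCT-116, whereas RKO had an FPKM of 0.00753 ± 0.011 and 0.439 ± 0.049 for them with DMSO. Except for the mitochondrially encoded genes, these lists passed with an estimated correlation, and the Wnt list missed the threshold in a voom fit on estimated fragments, chosen after seeing the data (adjusted p = 0.332).

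The other 4 lists passed with the preset correlation only. The integrated stress response was higher in RKO for 16 of 29 and lower for 3 (0.37, limma camera, adjusted p = 0.00401), or 17 and 3 adjusted over the list alone, and the adjusted p = 0.0957 with an estimated correlation. Its median was 0.21, with 13 higher and 3 lower, after the trend on GC content and length was removed, a fit chosen after seeing the data. EMT and adhesion genes were lower in RKO for 5 of 15 and higher for 3 on either adjustment (-0.41, adjusted p = 0.013), and the adjusted p = 0.149 with an estimated correlation. Histone genes were lower for 4 of 11 and higher for none on either adjustment (-0.30, adjusted p = 0.0212), and the adjusted p = 0.176 with an estimated correlation. Their median ranged from -0.88 without HCT-116 DMSO replicate 2 to -0.18 without HCT-116 PAA replicate 2. Cytosolic ribosomal proteins were lower for 2 of 26 on either adjustment, with a median of -0.06 that became 0.12 with a common total, 0.04 with quantile normalization and -0.14 with median-of-ratios factors (adjusted p = 0.0225), and the adjusted p = 0.436 with an estimated correlation. They also missed the threshold without RKO PAA replicate 2 (median -0.02, adjusted p = 0.142). Groups held 2 or 3 libraries, and RKO DMSO replicate 1 was not analysed here.

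**Figure D4:**
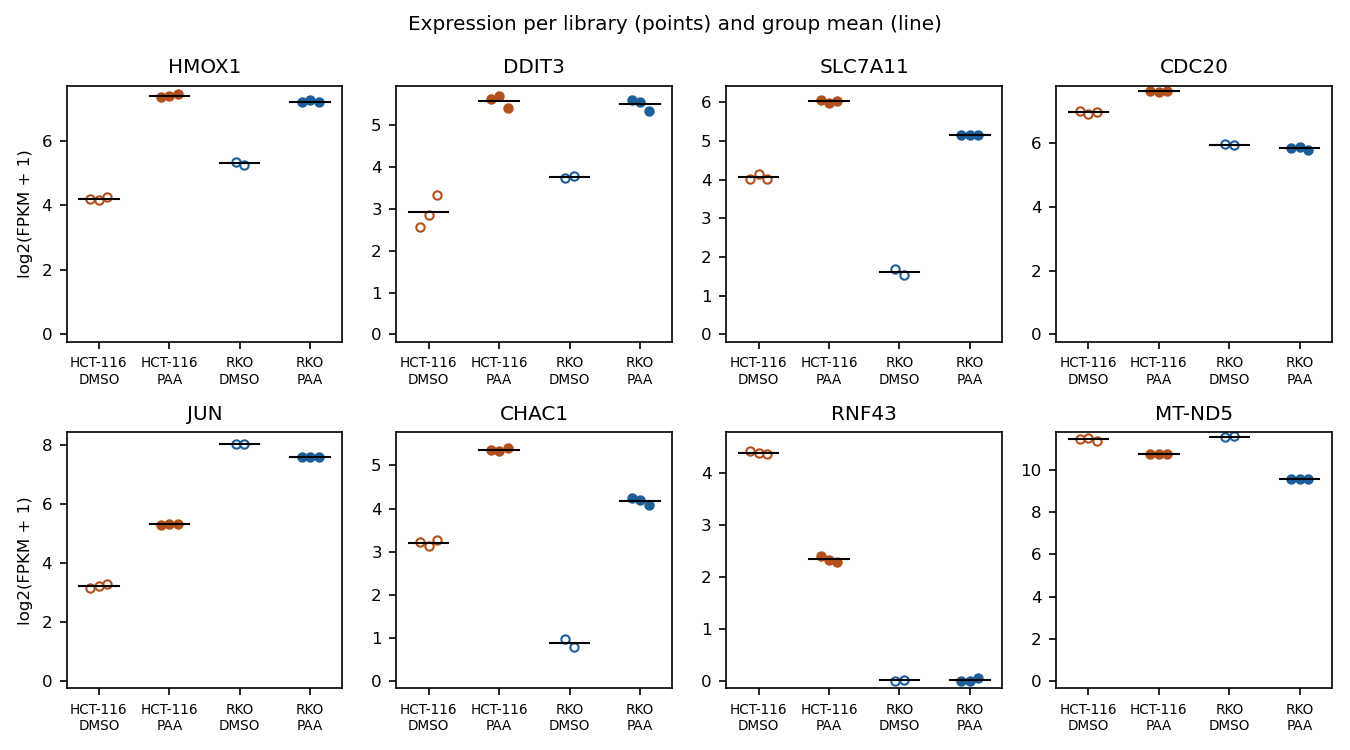
Log2(FPKM + 1) (vertical axis) of 8 genes in each library (points; open for DMSO, filled for PAA) with the group mean (line), for HCT-116 (orange) and RKO (blue). HMOX1, DDIT3, SLC7A11 and CHAC1 rise in both lines, JUN rises in HCT-116 and falls in RKO, RNF43 is near 0 in RKO, MT-ND5 falls more in RKO, and CDC20 rises in HCT-116 while its value in RKO falls by 0.12 or turns to 0.16 with a common total.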

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

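Among the 76 genes named here by the rule, the PAA effect differed between the lines for 59, 27 with a higher value in RKO and 32 with a lower one (limma interaction contrast, Benjamini-Hochberg). Values are RKO minus HCT-116 on the log2(FPKM + 1) scale. For 14 of the 59 the mean FPKM of 1 line was under 1 in both groups, so the gene was scarcely expressed there. In RKO these 10 were CYP4F11 (-3.06), SPRR2D (-2.96), AKR1B10 (-2.02), SOX9 (1.42), RNF43 (2.06), ALDH1A3 (2.26), CYP24A1 (3.23), ADAM19 (3.26), TNFRSF6B (3.29) and WNT16 (3.43). In HCT-116 these 4 were SST (-4.84), MAP1LC3C (-4.27), MT1M (-1.72) and TXNIP (-0.71). Genes that moved in opposite directions were JUN (-2.51), CCN1 (-2.22), the linker histone gene H1-2 (-2.16), MT1X (-1.47), MT2A (-1.21) and CDC20 (-0.78), where in RKO the fall of CDC20 turned to 0.16 with a common total and that of MT2A to 0.13 with quantile normalization.

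Genes that rose less in RKO were UPP1 (-2.07), SRXN1 (-2.03), PPP1R15A (-1.40), HMOX1 (-1.27), DDIT3 (-0.92), HSPA5 (-0.77), SQSTM1 (-0.69), TNFRSF10B (-0.48) and HMMR (-0.37), whose rise in RKO passed narrowly and not with median-of-ratios factors, quantile normalization or a common nuclear total (adjusted p = 0.172, 0.466 and 0.0639). Genes that rose more in RKO were SLC7A11 (1.56), SAT1 (1.54), ASNS (1.29), CHAC1 (1.14), BBC3 (0.86), WIPI1 (0.85), RELB (0.64), TRIB3 (0.54) and RRP12 (0.33). MIR22 (2.55), GABARAPL2 (1.26) and CD44 (0.80) rose in RKO and did not pass in HCT-116. Genes that fell further in RKO were METTL7B (-1.66), the pseudogene MTND4P12 (-1.46), MT-ND6 (-1.37), MT-ND5 (-1.32), MT-ND3 (-0.91), HSPE1 (-0.72), LDHA (-0.52) and CDK1 (-0.52), and H2AC20 (-1.09) and SERPINH1 (-0.73) fell in RKO and did not pass in HCT-116. Genes that fell less in RKO were NR2F1 (2.46, with 0.07 in RKO under a common total), SOX4 (2.32), HSPA1B (0.50), OAS3 (0.46), E2F2 (0.36), SDHA (0.34), POLR1B (0.34) and UTP20 (0.30). With a common total the RKO falls of SOX4, HSPA1B, POLR1B and UTP20 did not pass either (limma, adjusted p = 0.113, 0.71, 0.948 and 0.306). The differences of E2F2, POLR1B and UTP20 did not pass with quantile normalization (adjusted p = 0.11, 0.132 and 0.0655), nor those of E2F2 and POLR1B with median-of-ratios factors (adjusted p = 0.0705 and 0.121). Those of DDIT3, HSPE1 and TXNIP did not pass with a common total (limma, adjusted p = 0.0562, 0.0608 and 0.129), nor that of MIR22 with quantile normalization (adjusted p = 0.0771). The 11 lists that differed were the mitochondrially encoded genes (-0.83), metallothioneins (-0.80), mitosis and G2-M (-0.50), EMT and adhesion (-0.41), histones (-0.30), the unfolded protein response (-0.21), NRF2 targets (-0.19), cytosolic ribosomal proteins (-0.06, or 0.12 with a common total), the integrated stress response (0.37), p53 targets (0.37) and Wnt targets (0.68). The cause was not tested for these differences, except as follows.

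The tests of scaling for both lists, of equal loss of mitochondrial RNA and of swapped labels were chosen after the result was seen. Those of GC content and length, of single libraries and of YAP targets were written down before their own values were computed. The YAP list itself was written after the results were seen, so its test was not fixed ahead of the data. The 13 mitochondrially encoded coding genes fell in both lines and further in RKO. A wrong scaling factor per library or a bias by GC content and length could cause this, but the median in HCT-116, the weaker line, was -0.399 with a common total, the factor that moved its genes most, and -0.541 after the trend on GC content and length was removed. A loss of all mitochondrial RNA alike might also do so, but the 13 coding genes spanned 1.246 ± 0.0685 (SE) in RKO, from MT-ND6 to MT-ND1, and 0.455 ± 0.0701 in HCT-116, from MT-ND3 to MT-CYB. These ends were picked as the lowest and highest of the 13, and the SEs do not cover that choice. In HCT-116 the span exceeded the limit set for equal loss only narrowly, so the test is weak for that line. The rRNA gene MT-RNR2 rose by 0.85 in RKO and 0.18 in HCT-116, where it passed narrowly (limma, adjusted p = 0.0424). The other rRNA gene, MT-RNR1, rose by 0.59 in RKO and had -0.17 with no call in HCT-116 (adjusted p = 0.451). Of the 22 tRNA genes 18 were lower in RKO and 20 in HCT-116. A scaling that depends on the level of a gene stays open. Quantile normalization left a median of -0.151 in HCT-116, but it gives the highest ranks the same values in every library. The coding genes lie among those ranks, so a true fall would shrink too and this test cannot decide. The tRNA genes, at lower FPKM than the coding genes, had medians of -0.883 in HCT-116 and -0.708 in RKO. They are short and can adjoin other genes, such as MT-TF at positions 577 to 647, directly before MT-RNR1 at 648. Their reads are thus uncertain in source, and these medians do not decide the question either. A lower rate of mitochondrial transcription, faster decay of mRNA and a different recovery of rRNA between libraries also stay open.

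Mitotic genes fell in RKO but not as a list in HCT-116. Scaling might produce such a difference, but the weaker interaction median under median-of-ratios factors and quantile normalization was -0.577, and it was -0.353 with 20 of 30 lower under a common total. GC content and length, or a single library, could also do so, but the median was -0.543 after the trend was removed and -0.495 at its weakest with 1 library left out. A different position of the cells in the cycle after 24 h, a lower growth rate of RKO in PAA and other biological differences of the lines stay open.

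CCN1 and JUN rose in HCT-116 and fell in RKO. Swapped treatment labels in RKO could produce this, but the integrated stress response rose in both, with a lower median of 1.054. Opposite activity of YAP, the Hippo pathway coactivator, should give its other targets a clearly negative median difference between the lines. That rule was written before the list's median was computed, but after the results were seen. It should also give them a negative median in RKO. Their median difference was 0.074 and their RKO median 0.052, or -0.008 with median-of-ratios factors, so the prediction failed for the targets as a set. Single targets went both ways, with a difference that was higher for 5 and lower for 4 of 16 (limma), so a role for some of them stays open. Leaving the question open on that ground was not part of the written rule. AXL and CCN2, picked out after their values were seen, rose in HCT-116 and fell in RKO, with differences of -1.62 and -1.04, although the fall of CCN2 in RKO did not pass under a common total (adjusted p = 0.218). The high level of JUN in RKO with DMSO, and a control of part of these genes by AP-1, stay open too.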

How the results depend on the processing

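The counts held their size under most settings and shrank with stricter ones. With a mean FPKM of at least 5 as filter, 3806 genes passed in HCT-116, 3466 in RKO and 2335 in the difference between the lines. With an adjusted p under 0.01 these were 4816, 3809 and 2649, and 1922 genes were shared in direction. With an absolute log2 fold change of at least 1 they were 409, 286 and 398, and 69 were shared. The replicate number as a block gave 5658, 4058 and 2739, with 2131 shared. The numbers do not pair samples by these data, as the residuals of PAA and DMSO libraries with the same number had correlations of -0.142 to 0.067. Lists past the threshold were 6, 8 and 6 with an estimated correlation in place of 13, 15 and 11, and 25, 22 and 21 with fry. Leaving out 1 library at a time gave 5926 to 6484 genes in HCT-116, 4186 to 5533 in RKO, 3398 to 4012 in the difference and 2362 to 2774 shared, and 12 to 16, 14 to 15 and 10 to 13 lists. Each line fitted alone gives no value for the difference. With the sum of isoform values, ALDH5A1 and ATP5F1A changed sign in RKO, to 0.118 and 0.296 without a call, and POLR1B (-0.351) and ATP5F1A (-0.221) in HCT-116 and CD44 (0.686) and TXNIP (-0.577) in RKO lost their calls. Removing the trend on GC content and length, a fit chosen after seeing the data, moved list medians to -0.10 in HCT-116 and -0.25 in RKO for ribosome biogenesis, and in RKO to -0.17 for aldehyde metabolism, -0.20 for nuclear OXPHOS and 0.12 for cytosolic ribosomal proteins. In the difference between the lines it gave -0.30 for NRF2 targets, -0.16 for cytosolic ribosomal proteins and -0.54 for histones. A scaling to a common total ended the RKO calls of SOX4, HSPA1B, UTP20, POLR1B, BYSL, TXNIP, MT2A and NR2F1, the last with a value of 0.073. In the difference between the lines it ended those of DDIT3 (adjusted p = 0.0562), HSPE1 (0.0608) and TXNIP (0.129), and quantile normalization ended those of MIR22 (0.0771), UTP20 (0.0655), E2F2 (0.11) and POLR1B (0.132), the last 2 also with median-of-ratios factors (0.0705 and 0.121), by limma with Benjamini-Hochberg adjustment.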

Other observations

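The retinoic acid and YAP lists and the list of aminoacyl-tRNA synthetases were written after the results were seen, and the test of position along the mitochondrial genome was chosen after the result was seen. In HCT-116 the fall of ALDH1A3, which makes retinoic acid, came with falls of NR2F1 and DHRS3. DHRS3, a retinaldehyde reductase induced by retinoic acid, dropped from an FPKM of 9.52 to 0.719 (n = 3 each). CYP24A1, the enzyme that inactivates vitamin D, fell too, and what lowered it was not tested. Retinoic acid targets other than NR2F1 and DHRS3 fell as well. CRABP2, a carrier of retinoic acid, dropped from 104 to 31.3 and the nuclear receptor NR2F2 from 24.2 to 9.88. Of 11 such targets tested, 8 fell and none rose, with a median log2 fold change of -0.581 (limma camera, p = 0.000872, and p = 0.0101 with an estimated correlation, not adjusted over other lists). In RKO, which had an ALDH1A3 mean of 0.256 with DMSO, 3 rose and 1 fell, or 5 and 1 under a common total and 3 and 3 with median-of-ratios factors or quantile normalization. PAA may compete with retinaldehyde for ALDH1A3 or lower its transcription, and less retinoic acid could then lower its targets in HCT-116. Adding retinoic acid together with PAA would test this, and the order of these events is open.

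Many aminoacyl-tRNA synthetases, several of which are ATF4 targets, rose in both lines. CARS1, for cysteine, went from 8.64 to 16.0 in HCT-116 and from 3.73 to 11.3 in RKO, and AARS1, for alanine, from 24.1 to 43.9 and from 21.9 to 49.8. Of 18, 11 rose and 4 fell in HCT-116 (limma camera, p = 0.00307, and p = 0.0996 with an estimated correlation), and 10 rose and none fell in RKO (p = 1.38e-05, and p = 0.027 with an estimated correlation), not adjusted over other lists. Under a common total 11 rose and 1 fell in HCT-116 and all 18 rose in RKO.

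A fall of mitochondrial transcripts that grows with distance from the heavy-strand promoter could point to stalled transcription. The 12 coding genes of that strand had a Spearman correlation of log2 fold change with gene start of -0.126 in HCT-116 (permutation p = 0.699, 100000 resamples) and -0.573 in RKO (permutation p = 0.0568, adjusted p = 0.114). Distance alone may thus not account for the unequal falls of the coding genes in HCT-116, and in RKO the test leaves this undecided. The rRNA and tRNA genes were not part of the test. Of the 10 ways to split the 6 HCT-116 libraries into groups of 3, the real one alone reached 6532 genes, that is 1 split with as many, and the highest of the others reached 4, and 10 splits are too few for a permutation p under 0.05.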
